A study of Mus musculus with 2 samples.

How the data were processed

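The data were 2 ChIP-seq libraries, 1 for H3K4me2 and 1 for H3K4me3, from splenic B cells that had been enriched with magnetic anti-B220 beads and sorted as CD19-positive, CD21-intermediate and CD23-positive, per the labels' protocols. Cells were crosslinked with formaldehyde, and adapter-ligated fragments were amplified by PCR and selected by size on a gel, per the labels' protocols. The H3K4me2 antibody came from Millipore and the H3K4me3 antibody from Abcam, per the labels. Each library was assigned to its mark from its title.

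The authors deposited 1 list of aligned reads per library, with a chromosome, start, end and strand for each 35 bp read; the score column of the deposited lists was 0 in every line and was not used. Bowtie, HOMER and the assembly mm8 are named in the submitters' processing notes, with no version or setting. How reads with several alignments or identical positions were treated is not given in the sources used here. Reads of identical position are present in the lists, so they had not all been removed. Coordinates were taken as mm8 because those notes name it, and they were not converted to another build. No annotation of mm8 was used here, so the planned assignment of regions to start sites, promoters and lists of genes was not made. A RefSeq gene table of assembly GRCm38.p6 was used only to count protein-coding genes per chromosome, divided by the span of that chromosome in the reads, and none of its coordinates was used.

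Reads sharing chromosome, position of the 5′ end and strand were counted once, and the mitochondrial genome was left out, which gave 13532821 H3K4me2 and 12555089 H3K4me3 reads on chromosomes 1 to 19, X and Y. The shift between strands with the highest correlation on chromosome 1 was 175 bp for H3K4me2 and 170 bp for H3K4me3. Each 5′ end was moved 100 bp downstream and counted in 1000 bp windows (2630662 windows), with a mean of 5.14 reads per window for H3K4me2 and 4.77 for H3K4me3. A window was called enriched when its count was at least 4-fold over the mean window of its own library (21 reads for H3K4me2 and 20 for H3K4me3) and its one-sided Poisson p, adjusted by Benjamini-Hochberg over all windows, was at most 0.001. Enriched windows were joined over gaps of at most 1 window. Since the libraries have no control here, background due to copy number, alignability or open chromatin is not removed, and Poisson p-values describe 1 library.

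For ratios, the H3K4me2 and H3K4me3 regions were merged where they overlapped or touched, and log2 of H3K4me3 over H3K4me2 RPM (reads scaled to the library's total of distinct nuclear reads) was taken with a pseudocount of 1 read, for regions with at least 20 reads of both marks together. Intervals of shares are exact Clopper-Pearson intervals, intervals of medians are binomial order statistics, intervals of RPM are exact Poisson, and all are at 95%. For a count of 0, a floor of 3 reads was used. Profiles used 100 bp bins to 5000 bp either side of the mean position of the reads in a region, and their intervals came from 1000 bootstrap draws of regions. The distances that define centre and flank were set after seeing the profiles. Chance overlap was taken from 100 random rotations of the regions within their chromosomes. Correlations across chromosomes were tested with 100000 permutations. The caller was tested on simulated data: with 200 windows planted at each size among 2630662 Poisson windows, it called 98.5% of windows planted at 6-fold and 53.5% of those at 4-fold at the H3K4me2 depth. At the H3K4me3 depth these shares were 93.5% and 55.0%, and 1 background window was called at either depth. The simulated background had a single mean throughout, as the caller assumes, so false calls on an uneven background were not measured. Of 2000 simulated ratios, 95.6% lay within their interval. Those ratios had similar counts in both libraries and were not picked as extremes. How often the intervals hold for regions picked by extreme ratio was not measured.

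Regions were named by a rule fixed before the data were examined: the 5 widest and the 5 with the most reads of each mark, and the 5 highest and 5 lowest ratios among merged regions with at least 100 reads of both marks together. The alternatives also fixed then were counting all deposited reads, an 8-fold threshold, 500 bp windows, thinning H3K4me2 to the depth of H3K4me3, a 50% overlap, no shift of reads, the higher of the genome-wide mean and the mean of the surrounding 50000 bp as background, scaling to reads outside the regions, a pseudocount of 5 and no minimum of reads. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.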

Results

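Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 2 methylation states of lysine 4 of histone H3 in mature follicular B cells, the main recirculating B cell type of the spleen, sorted from adult wild-type C57BL/6 mice. H3K4me3, the trimethylated form, is known as a mark of active promoters, and H3K4me2, the dimethylated form, is found at promoters and at enhancers. The series held 1 library per mark, each made with its own antibody, and no input or control immunoprecipitation was analysed here. The H3K4me2 library held 17037570 aligned reads, of which 13533988 (79.4%) had a distinct position and strand. The H3K4me3 library held 16049576 reads, of which 12555462 (78.2%) were distinct. With 1 library per mark there were no replicates, so differences between the marks were given as values and not tested. The intervals below cover counting error or the spread over regions within these libraries, and none covers variation between libraries. PCR reads without molecular identifiers are not independent molecules, which these intervals do not take into account. Positions refer to the mouse assembly mm8. No annotation of that build was used, so regions are given by position and not by gene.

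The first question was how much of the genome was called enriched for each mark. H3K4me2 had more called regions than H3K4me3, and more wide ones. The call depends on how strongly each antibody enriched its mark. With 1 library per mark and no control, this cannot be separated from the extent of the marks. Outside the regions of both marks lay 83.3% of the H3K4me3 reads and 61.2% of the H3K4me2 reads. At a threshold of 4-fold over the library's own mean 1 kb window, 30138 regions were enriched for H3K4me2 and 13413 for H3K4me3. The H3K4me2 regions covered 88.8 Mb, or 3.38% of the spanned genome, and the H3K4me3 regions covered 26.2 Mb, or 0.995%. H3K4me2 regions held 38.7% of that library's distinct reads (95% exact binomial interval 38.7% to 38.8%), and H3K4me3 regions held 13.0% of theirs (13.0% to 13.0%). Both sets had a median width of 2 kb, but the sets differed in their wide members: 1054 H3K4me2 regions and 29 H3K4me3 regions were 10 kb or wider. Regions of a single window numbered 9959 for H3K4me2 and 5060 for H3K4me3. With the higher of the genome-wide mean and the mean of the surrounding 50 kb as background, the share of H3K4me2 reads inside regions was 22.1%; windows of broad domains count towards their own local background there.

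H3K4me3 lay almost wholly within H3K4me2 chromatin, whereas most H3K4me2 regions lacked called H3K4me3. Of the 13413 H3K4me3 regions, 12871 (96.0%, 95% exact interval 95.6% to 96.3%) overlapped an H3K4me2 region by at least 1 bp. Of the 30138 H3K4me2 regions, 12461 (41.3%, 40.8% to 41.9%) overlapped an H3K4me3 region and 17677 did not. When each chromosome's regions were rotated to a random offset, the mean overlap over 100 placements was 4.81% for H3K4me3 regions and 2.12% for H3K4me2 regions. The 542 H3K4me3 regions outside H3K4me2 regions were narrow, with a median width of 1 kb, and weak, with a median H3K4me3 level of 4.40-fold over the library mean (interquartile range 4.19 to 4.82).

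Regions with both marks carried more H3K4me2 than those with H3K4me2 alone. The median H3K4me2 level was 13.5-fold over the library mean (95% interval of the median 13.5 to 13.7) in the 12461 shared H3K4me2 regions, and 6.65-fold (6.61 to 6.80) in the 17677 unshared ones. Shared regions had a median width of 3 kb and unshared ones of 1 kb. In the unshared regions the median H3K4me3 level was 1.26-fold over the mean (interquartile range 0.978 to 1.78), compared with a mean of 0.862-fold in windows outside the regions of both marks. In H3K4me3 regions that overlapped H3K4me2, the median level was 12.2-fold for H3K4me3 and 18.2-fold for H3K4me2.

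The median H3K4me2 level was near or below the library mean in windows with H3K4me3 under 4-fold, and far above it in windows with more. Among 1 kb windows, this median was 0.389-fold, 0.778-fold and 0.972-fold where H3K4me3 was below 1-fold, 1- to 2-fold and 2- to 4-fold over its mean. These classes held 1476626, 986543 and 141661 windows. H3K4me2 still reached 4-fold or more in 1.09%, 2.94% and 11.3% of them, so many H3K4me2-rich windows had H3K4me3 under 4-fold. The median H3K4me2 level was 13.8-fold where H3K4me3 was 4- to 8-fold over its mean (9540 windows) and 18.5-fold where it was 8- to 16-fold (8399 windows). It was 21.6-fold where H3K4me3 was 16- to 32-fold (6934 windows) and 26.4-fold where it was 32- to 64-fold (946 windows). In the opposite direction, H3K4me3 increased with H3K4me2 mainly in the windows richest in H3K4me2. Its median was 1.26-fold in the 36506 windows with 4- to 8-fold H3K4me2 and 2.10-fold in the 28415 windows with 8- to 16-fold H3K4me2. It was 8.59-fold in the 19195 windows with 16- to 32-fold H3K4me2 and 18.4-fold in the 1619 windows with 32- to 64-fold H3K4me2. These medians are across windows of 1 pair of libraries, and windows are not replicates.

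**Figure D1:**
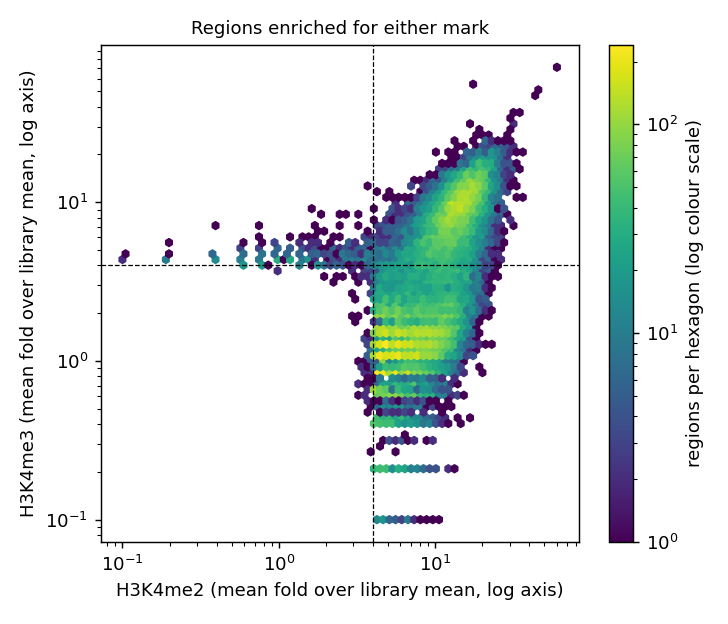
Mean level of H3K4me2 (x axis) and H3K4me3 (y axis) in each region enriched for either mark, as fold over each library's mean window on log axes, with values below 0.1 drawn at 0.1; colour gives the number of regions per hexagon on a log scale and dashed lines mark 4-fold. The median log2 H3K4me3 to H3K4me2 ratio was -2.34 in regions called for H3K4me2 only and -0.71 in regions called for both marks. It was 1.69 in regions called for H3K4me3 only. These classes follow from the 4-fold call, and whether regions form separate groups was not tested.

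The balance of the marks was then expressed as a log2 ratio of H3K4me3 to H3K4me2 reads, each scaled to its library's total of distinct nuclear reads (RPM), in the merged set of regions. The median was -0.71 (95% interval of the median -0.72 to -0.70) in 12527 merged regions with both marks and -2.34 (-2.35 to -2.33) in 17587 with H3K4me2 only. The zero of this scale is arbitrary, because the antibodies differ. Scaling to reads outside all regions lowered every ratio by 0.44. The classes were set by whether H3K4me3 was called, so part of the difference between them, 1.64, follows from their definition.

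H3K4me2 was higher at the shoulders than at the centre of the regions with the most H3K4me3. H3K4me3 regions were divided by the reads in their highest window into 4 groups of about equal size, numbered from the lowest, and centred on the mean position of their H3K4me3 reads. In group 1 (20 to 38 reads in the highest window, n = 3352 regions), H3K4me2 was 16.7 ± 0.218-fold (SE over regions) in the bins within 100 bp of the centre and 10.2 ± 0.135-fold at 400 to 600 bp to either side, a centre to flank ratio of 1.64 (95% bootstrap interval over regions 1.60 to 1.68). Group 2 had a ratio of 1.07 (1.04 to 1.10), which turned to 0.847 (0.813 to 0.881) when regions 2 kb wide alone were used. In group 3, H3K4me2 was 17.2 ± 0.218-fold at the centre and 21.8 ± 0.148-fold at the flanks, a ratio of 0.788 (0.766 to 0.810). Group 4 (106 to 650 reads) had 20.3 ± 0.237-fold at the centre and 25.01 ± 0.163-fold at the flanks, a ratio of 0.812 (0.791 to 0.834), and 63.3% of its regions had less H3K4me2 at the centre than at the flanks. The H3K4me3 ratio was 1.69 (1.65 to 1.73) in group 4, but a central summit of H3K4me3 is built in, since the regions were called and centred on H3K4me3. Group 1 had a median width of 1 kb and the other groups of 2 kb. Among regions 2 kb wide, a restriction chosen after seeing the data, the H3K4me2 ratio was 1.17 (1.09 to 1.24, n = 592 regions) in group 1, 0.673 (0.648 to 0.699, n = 1975) in group 3 and 0.677 (0.651 to 0.703, n = 1549) in group 4. H3K4me2-only regions, centred on their own H3K4me2 reads, had a centre to flank ratio of 1.73 (1.71 to 1.75), but their median width of 1 kb puts the flanks at the region edge. In the 2591 such regions of 3 to 4 kb the ratio was 1.082 (1.06 to 1.11), and 49.1% had less H3K4me2 at the centre than at the flanks. At the centre of all 17677 H3K4me2-only regions, H3K4me3 was 1.81 ± 0.0124-fold, against 1.31-fold about 5 kb away. The level 5 kb away was not the lowest nearby, since H3K4me3 fell to 1.02-fold or less on both sides between 2 and 3 kb from the centre.

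**Figure D2:**
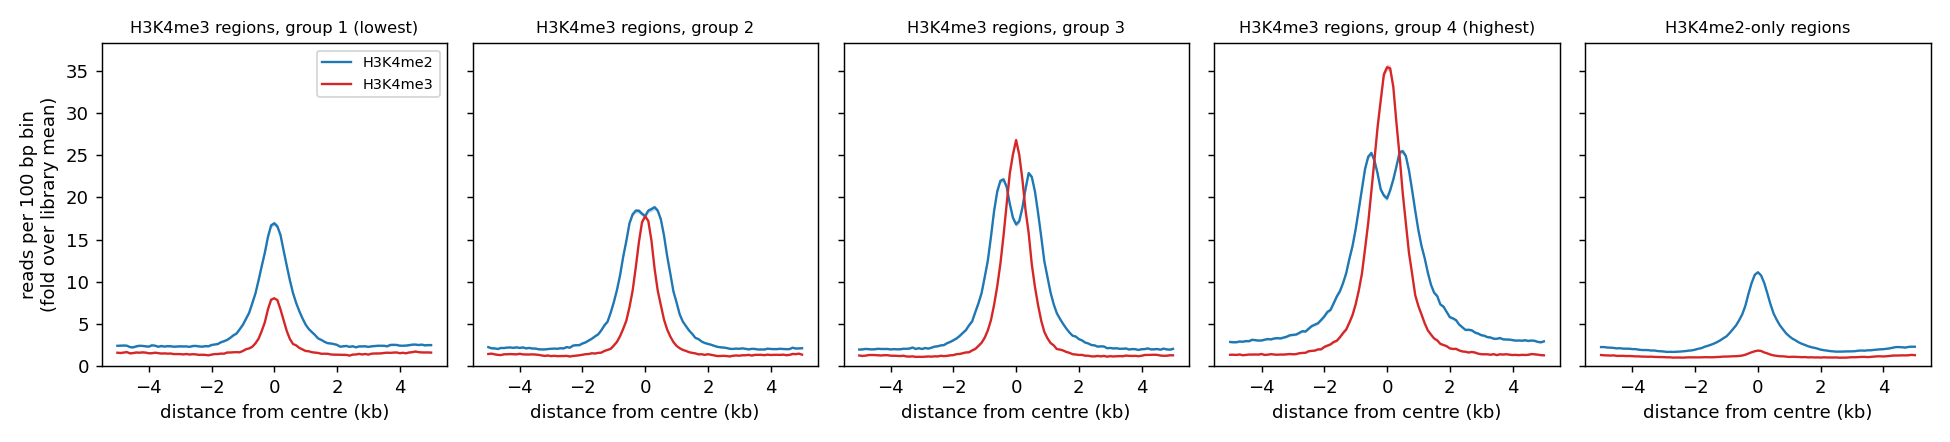
Mean read density in 100 bp bins (y axis, fold over each library's mean) against distance from the region centre in kb (x axis) for H3K4me3 regions in 4 groups of increasing H3K4me3 and for H3K4me2-only regions; lines are means over regions and shading is ± 1 SE. H3K4me2 has 1 summit in group 1 (centre to flank ratio 1.64) and 2 shoulders around the H3K4me3 summit in groups 3 and 4 (0.788 and 0.812).

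Broad H3K4me2 domains usually contained 1 or more H3K4me3 regions that took up a small part of their width. Of the 195 H3K4me2 regions of 20 kb or more, 177 (90.8%, 95% exact interval 85.8% to 94.4%) overlapped H3K4me3 and 86 overlapped 2 or more H3K4me3 regions, yet H3K4me3 regions covered on average 20.7% of the width over all 195. Among the 7547 regions of 3 to 4 kb, 65.7% (64.6% to 66.7%) overlapped H3K4me3, and the average width covered over all 7547, those without H3K4me3 included, was 38.5%. Of the 9959 single-window regions, 9.04% (8.48% to 9.62%) overlapped H3K4me3. The share was 44.4% in regions of 2 kb, 63.6% in those of 5 to 9 kb and 73.9% in those of 10 to 19 kb. Wider regions can overlap more readily by placement alone, and random overlap was not computed by width. H3K4me2-only regions were found close to H3K4me3 regions. The median distance between centres was 29.5 kb (28.5 to 30.0), and 66.1% (65.4% to 66.8%) lay within 50 kb of an H3K4me3 region. Randomly drawn windows outside the regions, equal in number per chromosome and with at least 1 read, had a mean of the medians of 146 kb over 100 draws, and 30.0% of them lay within 50 kb.

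Several broad H3K4me2 domains stood out by size. After a stretch near the start of chromosome 11, the widest was chromosome 9, 32236001 to 32295000 (59 kb). It had 344 RPM of H3K4me2 (95% Poisson interval 334 to 354) and 90.5 RPM of H3K4me3 (85.3 to 95.9), a log2 ratio of -1.93 (exact binomial interval -2.02 to -1.83). A second domain on that chromosome, 32443001 to 32500000 (57 kb), had 291 and 102 RPM of H3K4me2 and H3K4me3. The domain at chromosome 11, 118008001 to 118066000 (58 kb), held 372 RPM of H3K4me2 (362 to 382) and 80.1 of H3K4me3 (75.3 to 85.2), a log2 ratio of -2.21 (-2.31 to -2.12). Chromosome 1, 139940001 to 139997000 (57 kb), had 268 and 76.1 RPM, and chromosome 6, 48603001 to 48644000 (41 kb), had 286 and 108.

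**Figure D3:**
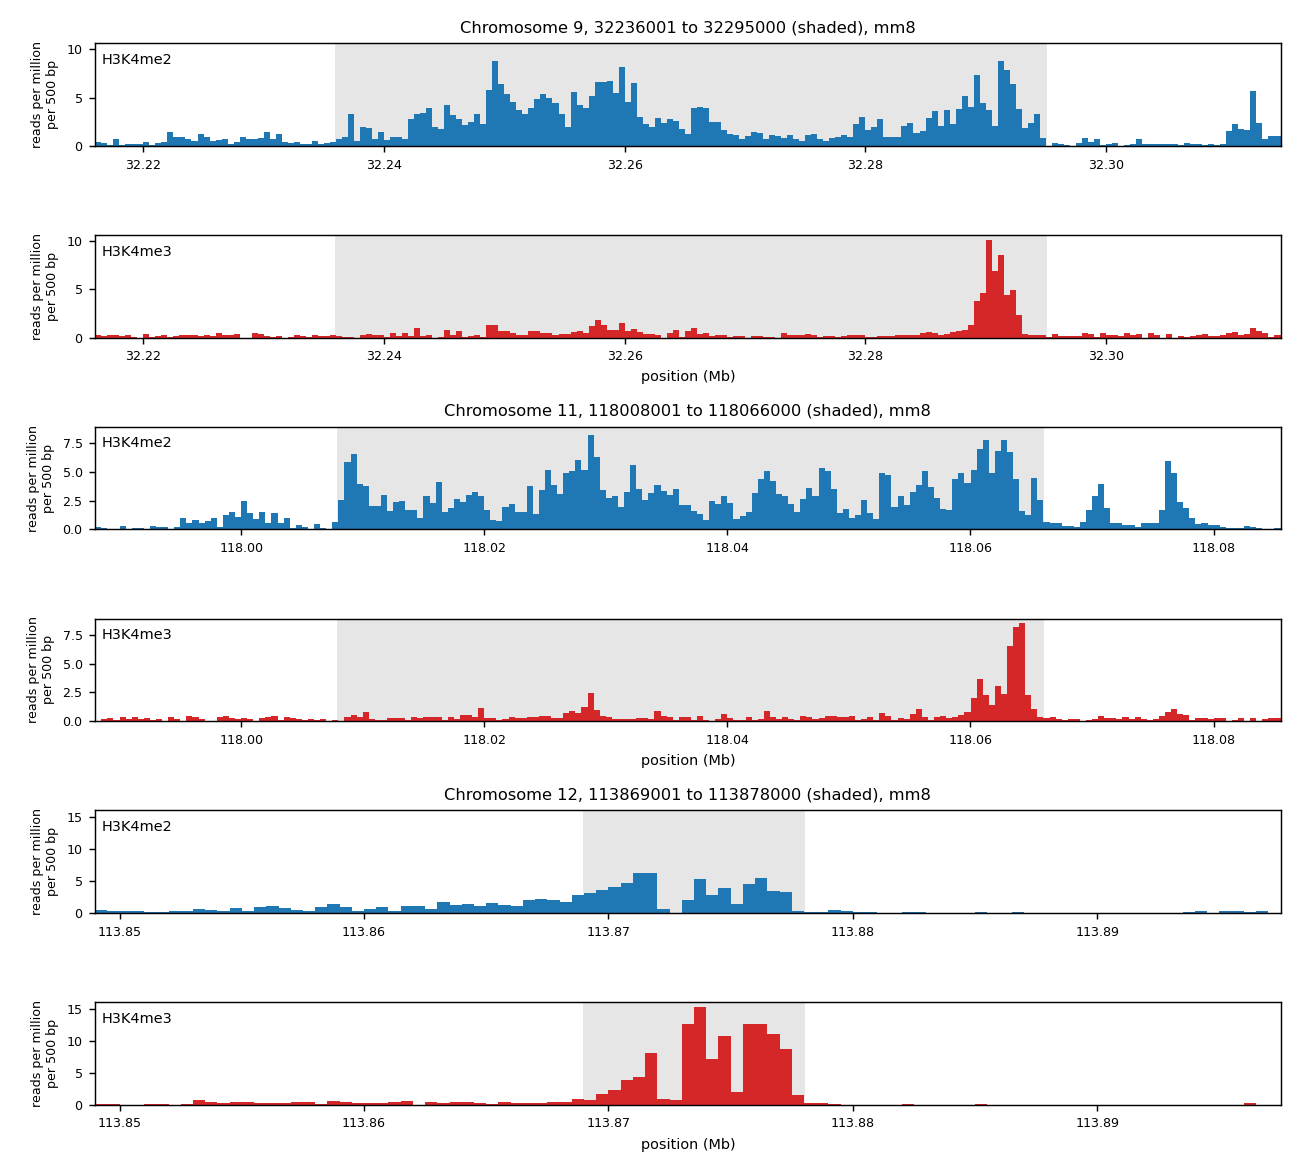
Read density in RPM per 500 bp (distinct reads) (y axis) of H3K4me2 (blue) and H3K4me3 (red) along 3 named regions (shaded) with 20 kb to either side; the x axis is the mm8 position in Mb, and both marks share a y scale within a region. In the domains on chromosomes 9 and 11, the 10 kb with the most H3K4me3 reads, which end 1 kb before the end of the domain, hold 57.9% and 56.6% of its H3K4me3 reads and 23.0% and 23.9% of its H3K4me2 reads; on chromosome 12, H3K4me3 is 34.1-fold and H3K4me2 17.9-fold over their library means.

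The widest H3K4me3 regions and those with the most reads were partly at positions where both libraries piled up alike. Chromosome 11, 3030001 to 3104000 (74 kb), was the widest and deepest, with 697 RPM of H3K4me3 (683 to 712) and 572 of H3K4me2 (559 to 585). The same stretch, at 3031001 to 3105000, was the widest and deepest H3K4me2 region. Chromosome 1, 90043001 to 90094000 (51 kb), had 115.7 and 111 RPM of H3K4me3 and H3K4me2. A neighbouring region at 90105001 to 90123000 (18 kb) had 70.3 and 77.3. The region at chromosome 9, 3015001 to 3039000 (24 kb), had 149 and 128 RPM, with 8.62 deposited H3K4me3 reads per distinct position against a median of 1.42 over H3K4me3 regions. Chromosome 2, 98463001 to 98469000, had 16.7 deposited H3K4me3 reads per distinct position and 119 and 101 RPM. Chromosome X, 165314001 to 165335000 (21 kb), had 62.8 RPM of H3K4me3 and 110 of H3K4me2. The remaining members of this group had higher ratios of H3K4me3 to H3K4me2: chromosome 12, 113869001 to 113878000 (9 kb), had 117 RPM of H3K4me3 (111 to 123) against 61.1 of H3K4me2 (57.0 to 65.4), and chromosome 17, 39451001 to 39457000 (6 kb), had 130 (124 to 136) against 39.2 (36.0 to 42.7). For comparison, autosomal 200 kb bins outside the regions had a median log2 ratio of 0.54, with 95% of them between -0.26 and 0.81, and the regions near the starts of chromosomes 11 and 9 and on chromosome 2 had ratios of 0.29, 0.22 and 0.24. The 20 kb after the chromosome 12 region held 40 H3K4me2 and 13 H3K4me3 reads, below the autosomal medians of 70 and 94.

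Among the 17640 merged regions with at least 100 reads of both marks together, the chromosome 17 region had the highest H3K4me3 to H3K4me2 log2 ratio, 1.72 (1.58 to 1.87). The next were chromosome 11, 108827001 to 108829000, at 1.67 (1.16 to 2.26), chromosome 2, 167380001 to 167382000, at 1.61 (1.00 to 2.32), chromosome 6, 51107001 to 51116000, at 1.57 (1.20 to 1.98), and chromosome 11, 88784001 to 88787000, with 167 H3K4me3 and 63 H3K4me2 reads (interval 1.09 to 1.96). The chromosome 17 region had 1.81 deposited H3K4me3 reads per distinct position, and the one at 108827001 had 2.53. The others had 1.19 to 1.36, against a 95th percentile of 1.73 over H3K4me3 regions. At the other extreme, chromosome 13, 83533001 to 83535000, had 105 H3K4me2 reads and 0 H3K4me3 reads. Set against a floor of 3 reads, the limit that a count of 0 allows, H3K4me2 was at least 32.5-fold higher there, a bound that leaves out the counting error of the 105 reads. The two-sided 95% counting interval of the log2 ratio, which includes it, reached up to -4.70 and so allows a smaller difference. Chromosome 2 held the next 3 lowest ratios, at 28339001 to 28341000 with 151 H3K4me2 and 4 H3K4me3 reads, at 160433001 to 160435000 with 128 and 4, and at 143865001 to 143867000 with 99 and 3 (log2 ratio -4.54, interval -7.24 to -3.35). Chromosome 9, 110308001 to 110310000, had 98 and 3 reads, a log2 ratio of -4.52 (-7.22 to -3.33). The intervals within each extreme overlapped, so their order was not resolved at this depth. Neither these intervals nor the 32.5-fold bound allow for the regions being picked as extremes among 17640. In the 5 lowest regions, H3K4me3 was 0 to 0.419-fold over its library mean. That is below the mean of 0.862-fold in windows outside the regions of both marks.

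Both marks were denser on gene-rich chromosomes. H3K4me2 regions ranged from 8.33 per Mb on chromosome 14 to 18.3 per Mb on chromosome 11 among the autosomes (mean 12.2 ± 2.53, SD over 19 autosomes), and H3K4me3 regions from 3.55 to 9.22 per Mb on the same chromosomes (mean 5.39 ± 1.495). Across chromosomes 1 to 19 and X, the density of protein-coding genes correlated with H3K4me3 regions per Mb with Pearson r = 0.877 (permutation p = 1e-05, adjusted 3e-05) and Spearman rho = 0.938 (p = 1e-05, adjusted 3e-05), where 1e-05 is the smallest p these permutations can give. For H3K4me2 regions, r was 0.755 (permutation p = 7e-05, adjusted 0.0001) and rho 0.865 (p = 2e-05, adjusted 3e-05). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.909 for H3K4me3 and 0.803 for H3K4me2. The number of H3K4me2 regions per H3K4me3 region was lower on gene-rich chromosomes, with r = -0.594 (permutation p = 0.0056, adjusted 0.0056) and rho = -0.594 (permutation p = 0.0068, adjusted 0.0068); r was -0.415 without chromosomes 7 and 11 and -0.816 without X. The adjustment covered these 3 relations, all tests were two-sided, and chromosomes are not replicates.

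**Figure D4:**
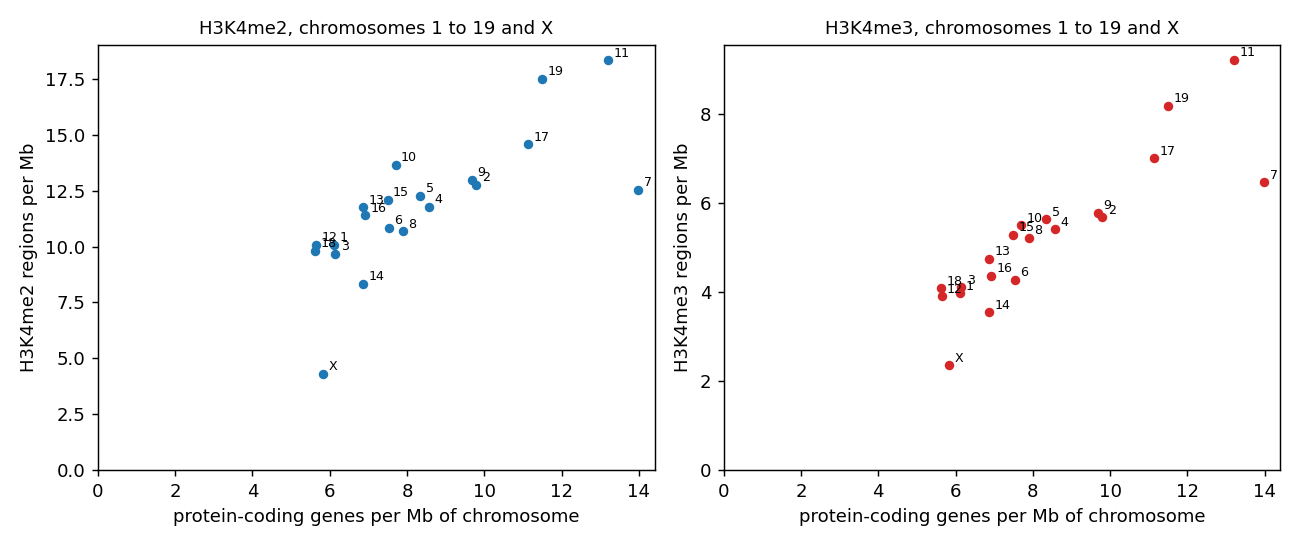
Enriched regions per Mb (y axis) of H3K4me2 (left) and H3K4me3 (right) against protein-coding genes per Mb (x axis), 1 labelled point per chromosome. Density increases with gene density for both marks (r = 0.755 and 0.877), and X is the lowest point in each panel (4.31 and 2.36 regions per Mb). Read depth of X outside the regions was 41.2% (H3K4me2) and 40.6% (H3K4me3) of the autosomal mean, while the threshold was genome-wide.

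The X chromosome had the fewest regions per Mb, 4.31 for H3K4me2 and 2.36 for H3K4me3, which is 0.355 and 0.437 of the autosomal means. Its read depth outside the regions was 41.2% of the autosomal mean in the H3K4me2 library (1.40 against 3.398 ± 0.167 reads per window, SD over 19 autosomes) and 40.6% in the H3K4me3 library (1.74 against 4.29 ± 0.175). Windows of X thus needed a higher enrichment over the depth of X to reach the genome-wide threshold. An alternative chosen after seeing the data set X windows against the mean of the X chromosome itself. X then had 6.13 H3K4me2 and 3.06 H3K4me3 regions per Mb, against lowest autosomal values of 8.33 and 3.55. These values were not called alike, because at the lower depth of X the adjusted p can ask for more than 4-fold. Whether X is poorer in regions at equal depth was not tested.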

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

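Mitochondrial reads, which no comparison used, were above the limit that a count of 0 allows in both libraries. The H3K4me2 library held 3315 such reads, 0.0195% of its reads (95% exact interval 0.0188% to 0.0201%), and the H3K4me3 library held 546, 0.00340% (0.00312% to 0.00370%). Counted once per position and strand, they were 1167 and 373 reads. The intervals treat repeated reads as independent.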

How the results depend on the processing

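Chosen only after seeing the data were the tests that left out regions with more than 2 reads per position, that counted all reads or took regions 2 kb wide for the centre to flank ratio, and that set X windows against the mean of X. The numbers of regions stayed within 1.5 times of 30138 and 13413 under each alternative run, from 21309 and 10040 at 8-fold to 38677 and 16291 with 500 bp windows. The share of H3K4me3 regions overlapping H3K4me2 (96.0%) was 92.9% with all deposited reads, 97.51% at 8-fold, 87.3% with 500 bp windows and 91.3% with a local background. The share of H3K4me2 regions overlapping H3K4me3 (41.3%) was 45.4% at 8-fold, 35.7% with 500 bp windows, 30.1% when 50% of the width had to be covered and 48.1% with a local background. The share of H3K4me2 reads in regions (38.7%) was 42.6% with all reads, 30.9% at 8-fold, 38.3% with 500 bp windows, 38.5% after thinning, 38.7% (38.683%) with reads not moved and 22.1% with a local background. That of H3K4me3 reads (13.0%) was 15.8%, 10.96%, 12.9% and 11.1% with all reads, 8-fold, 500 bp windows and a local background. Leaving out regions with more than 2 reads per position gave 38.7% (38.656%) and 12.8%. The median log2 ratio of regions with both marks (-0.71) was -1.15 scaled to outside reads, -0.69 (-0.685) with a pseudocount of 5 and -0.70 (-0.698) with all reads. That of H3K4me2-only regions (-2.34) was -2.79, -1.92 and -2.43, and the difference (1.64) was 1.24 with the larger pseudocount and 1.73 with all reads. The H3K4me2 centre to flank ratio of the group richest in H3K4me3 (0.812) was 0.841 with all reads and 0.677 in regions 2 kb wide. The other 30 values moved by less than their interval or, for counts, by less than 1.5 times. None of these values changed sign, and the causes of these shifts were not tested. The planned settings of promoter width, start site and distance to a start site were not run, because no mm8 annotation was used. No paired analysis was possible because each mark had 1 library, and for that reason no library could be left out. Membership of the H3K4me2-only class rests on the 4-fold rule, and 17.8% of its regions had H3K4me3 above 2-fold. Depth limited the order of the highest and lowest ratios, whose intervals overlapped.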

Other observations

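Chosen only after the result was seen were the tests on the 5 regions with the most H3K4me3 reads and on the order of the 4 groups of H3K4me3 regions; the count of all reads at the centre, the restriction to regions 2 kb wide, the use of reads per position and the bounds of the chromosome 12 stretch were also set after the patterns had been noticed.

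H3K4me2 was lower at the centre than at the shoulders of the regions richest in H3K4me3. Counting each position once does not account for it, since the centre to flank ratio was 0.841 (95% bootstrap interval 0.787 to 0.921) with all deposited reads. Whether centring makes the dip stays open, because the dip was seen in regions centred on H3K4me3 reads and the test centred on H3K4me2 reads. Centring on H3K4me2 reads made no dip in H3K4me2-only regions of 3 to 4 kb, where the ratio was 1.082 (1.06 to 1.11). Those regions also carried less H3K4me2 than the regions of that width with both marks. In regions of that width with both marks, centred the same way, the ratio was 0.933 (0.914 to 0.954), and 54.6% had a lower centre. Few alignable or recoverable fragments at the centre stay open: a ratio of H3K4me3 above 1 was to exclude them, but the 1.53 (1.498 to 1.57) in the latter regions is built in where regions are chosen for H3K4me3, and that ratio was 2.36, 2.42, 2.07 and 1.69 in groups 1 to 4 and 1.71, 2.18, 1.99 and 1.86 at a width of 2 kb. That trimethylation takes the place of dimethylation at the centre remains a hypothesis, which may explain the fall from 1.64 to 0.788 over the lower 3 groups (1.17 to 0.673 at 2 kb) but is left open by the richest one, at 0.812, whose interval overlaps that of group 3.

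Of the 5 regions with the most H3K4me3 reads, 3 had a mark ratio like that of the genome outside the regions, where 95% of 11804 autosomal 200 kb bins lay between -0.26 and 0.81 (median 0.54, log2 H3K4me3 to H3K4me2). With ratios of 0.22 at the start of chromosome 9 and 0.24 on chromosome 2, and 8.62 and 16.7 H3K4me3 reads per distinct position there, many copies of an unmarked repeat placed on 1 position may be the source of these pile-ups. The chromosome 11 region had a ratio of 0.29 but 1.59 reads per position, below the 95th percentile of H3K4me3 regions (1.73), which leaves that explanation open for it. The chromosome 17 region, at 1.72 (1.58 to 1.87), lies outside that range, which argues against unmarked copies alone, although copies that carry H3K4me3 stay open. It had 1.81 H3K4me3 reads per distinct position, above the 95th percentile of 1.73. For the chromosome 12 region, at 0.93 (0.81 to 1.06), the interval reaches the edge of the range and leaves the question open.

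The 20 kb after the chromosome 12 region held 40 H3K4me2 and 13 H3K4me3 reads, and 13.2% and 5.57% of autosomal 20 kb stretches held as few, while the 20 kb before the region were enriched, with 494 and 160 reads (97.3% and 92.5% held as few). From 114000001 to 116400000, the mean depth was 33.0% of the autosomal median for H3K4me2 and 23.3% for H3K4me3, with 6 H3K4me2 regions and 0 H3K4me3 regions called. The heavy chain locus of immunoglobulin, which loses DNA by rearrangement in B cells, is known to lie towards the distal end of this chromosome, so lost DNA is a candidate explanation, but the position of that locus in mm8 was not used here. The 90th percentile of reads per window was 3.0 for H3K4me2 and 33.3% of the autosomal value for H3K4me3, below X (4.0 and 44.4%). A value under 50% was to exclude unalignable sequence alone, but low stretches on chromosomes 3, 13 and 19 had 37.5% each for H3K4me2 and 44.4%, 33.3% and 55.6% for H3K4me3, and with alignability measured in none of them, lost DNA and unalignable sequence cannot be told apart here.

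The Y chromosome, of which 2.73 Mb was spanned, had 1.02 H3K4me2 and 1.21 H3K4me3 reads per window outside the regions, and the labels do not give the sex of the mice.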
